A study of Mus musculus with 43 samples.

How the data were processed

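The series compares neurons of the frontal cortex from Swiss Webster mice kept in environmental enrichment (EE: larger cages with a running wheel, a tube, extra nesting and toys that were exchanged every few days) or in standard housing (SH). Mice were weaned at postnatal day 25 and were 2 months old when the tissue was taken. Nuclei were fixed with paraformaldehyde, stained for the neuronal protein NeuN and sorted, and each sorted sample gave either a nuclear RNA-seq library or an ATAC-seq library, which marks open chromatin by where a transposase can insert adapters. The 43 libraries form 8 groups: 6 EE and 6 SH libraries for female RNA and the same for male RNA, 3 EE and 3 SH libraries for female ATAC, and 6 EE and 7 SH libraries for male ATAC. Groups follow the labels. The labels do not say that replicates are separate animals, so a p from a comparison of libraries measures the spread between these samples. Fisher's exact and binomial tests count genes or regions instead. Camera, a test of gene lists, takes the members of a list as nearly independent when its correlation is preset. Each sex and assay has its own table, and female and male libraries carry different run names, so sex and run cannot be told apart.

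The deposited RNA tables hold raw read counts per Ensembl gene over introns and exons, with no normalization by the authors, and the deposited ATAC tables hold raw counts per region, with 1 set of regions per sex. Per the submitters' processing notes, STAR 2.5.4, DESeq2 1.16.1, SAMtools 1.3.1, bedtools, MACS2 2.1.1, edgeR and DiffBind 3.2.2 were used with genome build mm10. The read counter, the read filters and the way regions were merged are not given in the sources used here. The header of the male RNA table is 1 name short, so its columns were taken by position. Whether the region starts count from 0 or 1 is not given either, and coordinates are printed as they stand in the tables.

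Total counts in mega (M) ran from 10.6 to 15.4 M per female RNA library, 10.4 to 14.6 M per male RNA library, 19.1 to 26.3 M per female ATAC library and 27.7 to 73.8 M per male ATAC library. In counts simulated with the spread of each table, log2 changes of 0.5 or 1 were planted in 200 genes or regions. Each gene or region was drawn independently, without differences that libraries share across genes. A log2 change of 0.5 was called in 53.5% of changed genes for female RNA and 68.4% for male RNA, and in 6% of changed regions for female ATAC and 26% for male ATAC. A log2 change of 1 was called in 82.7%, 91.7%, 54% and 90% of them in the same order.

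Of 53379 gene IDs, 53274 matched a symbol. Each table was fitted alone in edgeR 4.0.16 under R 4.3.3 with trimmed-mean (TMM) scaling, the default low-count filter of edgeR and a robust quasi-likelihood F test of housing, and a gene or region was called at a Benjamini-Hochberg adjusted p under 0.05. A positive log2 fold change means higher in EE. The standard error (SE) of a log2 fold change is its size divided by the square root of F. Levels are counts per M (CPM), given as mean ± SD. Regions were assigned to the protein-coding gene with the nearest start.

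Before the data were examined, 25 gene lists, the tests, the rule for naming genes and most alternatives were fixed. The lists covered immediate early genes, delayed activity-regulated neuronal genes, the excitatory postsynaptic density, the presynaptic vesicle cycle, voltage-gated channels, GABAergic interneurons, upper-layer and deep-layer excitatory neurons, striatal projection neurons, astrocytes, oligodendrocytes, their precursors, microglia, vascular cells, the nuclear-encoded respiratory chain, mitochondrially encoded genes, cytosolic ribosomal proteins, heat shock and protein folding, glucocorticoid-responsive genes, the circadian clock, chromatin regulators, neurotrophic and growth factor signalling, perineuronal nets and extracellular matrix, high-confidence autism genes, and sex label check genes. The last served only to check labels, and the mitochondrially encoded genes had a count of 0 in every RNA library, which left 23 lists to test. Each was tested with camera in limma 3.58.1 (two-sided, preset inter-gene correlation 0.01, adjusted over the lists), with an estimated correlation and with fry beside it. For ATAC, a list comprised the regions whose nearest gene start, within 100 kb, belonged to a member.

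Named genes are, per sex, up to 12 called genes with the largest change in each direction and an average log2 CPM of at least 1 (if none passed, the 5 with the smallest p in that direction), without symbols of the form Gm or Rik, plus up to 4 members of each list with the smallest p. Named regions are the 8 called regions with the smallest p in each direction (if none passed, 3) and called regions nearest to a list gene. Interaction genes are up to 10 with the smallest p among those called.

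The sexes were compared by a sex by housing interaction in 1 fit of all RNA libraries, and by correlating log2 fold changes across genes, or across regions that overlap by at least 50% of both, against 100 relabellings of housing. RNA and promoter changes were correlated in the same way, with a promoter region lying within 1 kb of the start of any annotated gene. Measures of the libraries were compared by exact permutation tests, two-sided. For each count of called genes, regions or lists, other splits of the same libraries into groups of the same sizes were fitted too: all 10 for female ATAC, 24 drawn for male ATAC and 100 drawn for RNA.

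Alternatives were DESeq2 size factors, scaling by total count alone, no count filter, a stricter filter at 1 CPM, the DESeq2 1.42.0 Wald test, limma voom with quality weights, 1 surrogate variable (sva 3.50.0), a threshold of 0.1, the replicate number as a block, leaving out each library, removal of ribosomal and mitochondrial RNA genes (RNA), and loess offsets, autosomes only and promoter regions only (ATAC). Chosen after seeing the data were the striatal and non-neuronal marker levels as covariates, a joint fit of both sexes, leaving out libraries for the lists and for the interaction, male ATAC without SH libraries 5 and 6 (picked for their place on the first principal component), the nearest gene of any class, a common effect of housing across sexes, counts summed over gene bodies and a list of sterol synthesis genes. Overlaps were computed with GenomicRanges 1.54.1, and figures were drawn with matplotlib 3.10.9 under Python 3.11. Correction for GC content and the motif content of regions were not analysed here, because a genome sequence was not used here.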

Results

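Nuclear RNA and open chromatin of sorted cortical neurons were measured in females and males after enrichment or standard housing. There were 6 EE and 6 SH libraries for RNA in each sex, 3 EE and 3 SH libraries for female ATAC, and 6 EE and 7 SH libraries for male ATAC. The RNA matched the sex given in the labels: Xist, the RNA that coats the inactive X chromosome, had 6340 to 9857 counts in female libraries and 0 to 3 in male libraries. Markers of glia and vessels were detected in these NeuN-sorted nuclei. Female SH replicate 2 stood apart, with a mean log2 level of 1.29 for the non-neuronal lists together against the average of the female libraries. Of the measures of library quality compared between EE and SH, the number of genes detected in male RNA differed most (25104.5 ± 1321 in EE and 26647 ± 785 in SH, SD, n = 6 each; exact permutation p = 0.0368, adjusted p = 0.515 over 14 comparisons). In female RNA the first principal component (24.9% of the variance) followed that library, and the second (11.1%) parted EE from SH (exact permutation p = 0.00216, the smallest that 924 arrangements can give, not adjusted). Components 1 and 2 did not part them in male RNA (23.6% and 13.4%, exact permutation p = 0.134 and 0.931).

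The first comparison asked which nuclear RNAs differ with enrichment in neurons of females. Immediate early genes, the transcripts that neurons switch on soon after they are active, were higher in EE as a group: all 20 measured members had a positive log2 fold change, with a median of 0.67. Fosb, a subunit of the AP-1 transcription factor, averaged 1.46 ± 0.56 CPM in EE and 0.46 ± 0.36 in SH (SD, n = 6 each; log2 fold change 1.63 ± 0.40, SE). Npas4, an activity-dependent transcription factor, averaged 22.1 ± 4.68 CPM in EE and 11.1 ± 4.04 in SH (1.00 ± 0.24). Both genes lay above the SH median in 6 of 6 EE libraries. Egr1, a zinc finger transcription factor, had a log2 fold change of 0.91 ± 0.28 and Btg2, a regulator of mRNA turnover, one of 0.68 ± 0.24. The camera test of the list gave an adjusted p of 3.82e-14, but adjusted p = 0.255 with an estimated correlation and adjusted p = 0.154 with fry. Of its members, 8 passed when adjusted over the list alone and 0 over all genes. The level of the list per library averaged 0.34 ± 0.30 in EE and -0.34 ± 0.45 in SH (SD, exact permutation p = 0.0130, adjusted p = 0.156 over the lists). SH replicates 1 and 4 were lowest (-0.90 and -0.89, against -0.29 to 0.11 in the other 4), and without both the median log2 fold change of the list was 0.43 (exact permutation p of the level = 0.0524), in an analysis chosen after seeing the data.

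**Figure D1:**
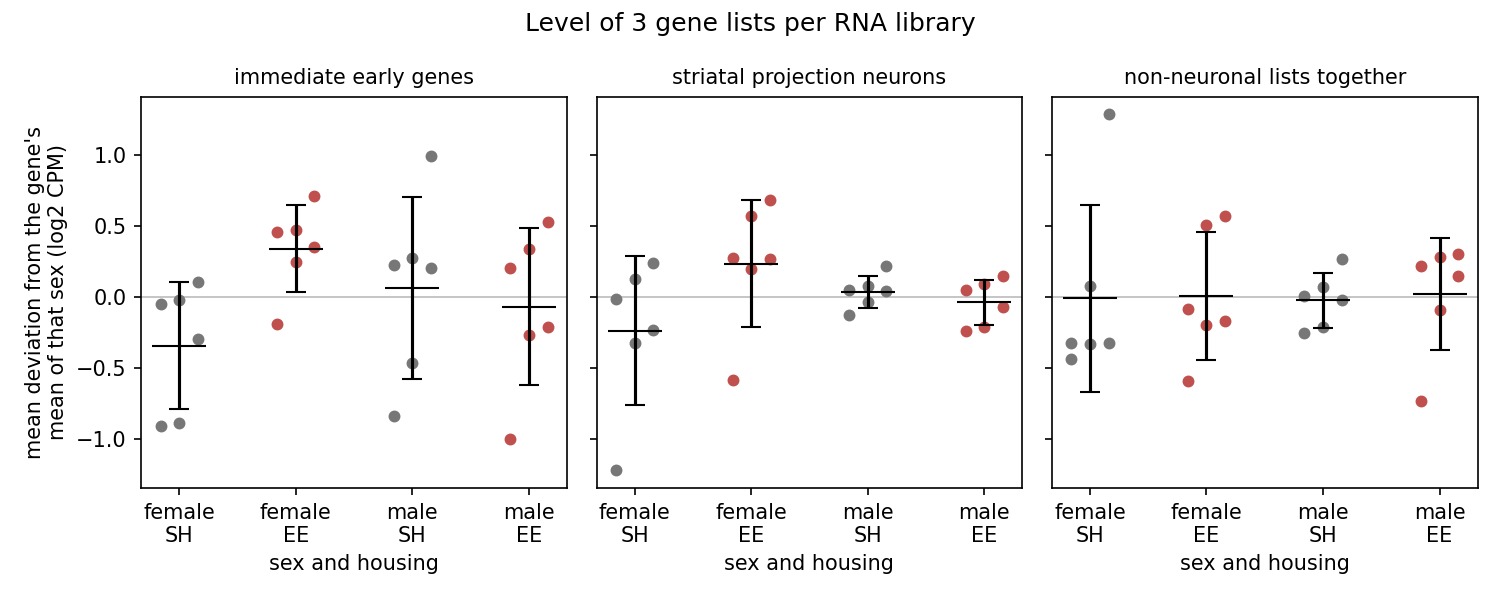
Level of 3 gene lists in each RNA library: the y axis is the mean log2 CPM of the list's genes, each centred on the libraries of that sex, points are libraries, and bars are the mean with SD of 6 libraries per group. Immediate early genes averaged 0.34 in female EE and -0.34 in female SH libraries, and the non-neuronal level of female SH replicate 2 was 1.29.

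Markers of striatal projection neurons were higher in female EE libraries as well (17 of 19 genes, median 0.52, camera adjusted p = 3.86e-05, adjusted p = 0.696 with an estimated correlation). Tac1, the precursor of substance P, averaged 4.10 ± 1.45 CPM in EE and 1.71 ± 0.88 in SH (SD, n = 6 each). Isl1, a transcription factor of developing striatal neurons, had a log2 fold change of 1.54 ± 0.49. Tac1 and Isl1 passed when adjusted over the list alone, and 0 genes did over all genes. Pde10a, the most abundant marker named, was at 1265 CPM in EE and 1485 in SH (log2 fold change -0.23 ± 0.11). The level of this list spread from -1.22 to 0.68 between female libraries, with an exact permutation p of 0.126 for housing. Its median was 0.33 without EE replicate 1, 0.32 without EE replicate 3 and 0.32 without SH replicate 5.

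Markers of upper-layer excitatory neurons were lower in female EE libraries as a group (14 of 19 genes, median -0.11, camera adjusted p = 0.0437, adjusted p = 0.638 with an estimated correlation). Cux2, a homeobox factor of upper layers, had a log2 fold change of -0.19 ± 0.05, whereas Cartpt, a neuropeptide precursor, had 0.97 ± 0.26 and Cntnap5a, an adhesion molecule, 0.22 ± 0.05. These 3 genes passed when adjusted over the list alone and 0 over all genes. High-confidence autism genes were lower too (45 of 61, median -0.04, adjusted p = 0.0198, adjusted p = 0.696 with an estimated correlation), with Tbr1 at -0.23 ± 0.09 and Ptprt at -0.15 ± 0.05. The 1 member that passed when adjusted over the list alone, the histone demethylase gene Kdm6b, was at 0.36 ± 0.09. Scaling by total count alone, or leaving out EE replicate 6, ended the calls of these 2 lists. The upper-layer call also ended without EE replicate 1 or 3 or SH replicate 3 or 5, and the autism call without SH replicate 1 or 4. The number of female lists past the test was 8 without EE replicate 4, 2 without EE replicate 6 and 13 without SH replicate 2.

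The other 19 lists did not pass in female RNA. Synaptic and channel lists had most genes lower. These were 27 of 40 genes of the postsynaptic density (adjusted p = 0.0664; Camk2a -0.15 ± 0.05, Grin2a -0.15 ± 0.05) and 29 of 39 of the presynaptic vesicle cycle (adjusted p = 0.212; Stx1a -0.16 ± 0.05, but Syn3 0.21 ± 0.05). So were 28 of 37 voltage-gated channel genes (adjusted p = 0.0714; Kcnn2 -0.25 ± 0.08). Of GABAergic markers 19 of 31 were higher (adjusted p = 0.0664; Sst 0.35 ± 0.13), and of deep-layer markers 17 of 26 (adjusted p = 0.765). Of delayed activity-regulated genes 19 of 36 were higher (adjusted p = 0.764; Sorcs3 -0.25 ± 0.06), and of glucocorticoid-responsive genes 13 of 16 (adjusted p = 0.150; Sgk1 0.15 ± 0.05, Nr3c1 -0.19 ± 0.06). Ribosomal protein genes (37 of 63 higher, adjusted p = 0.196), respiratory chain genes (45 of 72, adjusted p = 0.345) and heat shock genes (13 of 27, adjusted p = 0.765; Hspa8 0.59 ± 0.19) did not differ detectably. The clock (10 of 21 higher, adjusted p = 0.586; Hlf -0.20 ± 0.05) and chromatin regulators (35 of 80, adjusted p = 0.586; Hdac5 0.28 ± 0.06, Smarca2 -0.21 ± 0.05) held members of both signs. So did neurotrophic signalling (15 of 28, adjusted p = 0.764; Ntrk2 -0.16 ± 0.06) and perineuronal nets (16 of 29, adjusted p = 0.764; Tnr -0.17 ± 0.05). Among non-neuronal lists, 7 of 24 astrocyte genes (adjusted p = 0.768; Bmpr1b 0.53 ± 0.11), and 3 of 21 oligodendrocyte genes (adjusted p = 0.409) were higher in EE. The same held for 4 of 13 precursor genes (adjusted p = 0.765), 2 of 15 microglial genes (adjusted p = 0.212) and 7 of 18 vascular genes (adjusted p = 0.765). The direction of the astrocyte and oligodendrocyte lists rested on SH replicate 2. Without it 20 of 24 astrocyte genes (median 0.27) and 18 of 21 oligodendrocyte genes (0.35) were higher, and with limma 16 and 14 were (medians 0.14 and 0.16). For astrocyte and vascular genes camera pointed higher although the medians were -0.16 and -0.02. The mean had the other sign than the median for heat shock genes (mean 0.05, median -0.00), the clock (0.01, -0.01), chromatin regulators (0.00, -0.02) and neurotrophic signalling (-0.00, 0.01), and camera took the sign of the mean for the first and last of these. Adjusted over the list alone, 6 chromatin regulators, 2 astrocyte genes, 2 delayed activity-regulated genes and 1 gene each of the presynaptic, clock and precursor lists passed, against 0 over all genes.

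In a fit of housing alone, which did not pair libraries by number, edgeR called no single gene in female RNA. This was 0 of 14587 tested, with 1265 at an unadjusted p under 0.05, while DESeq2 called 117 and limma 19. With 1 surrogate variable edgeR called 42, and 36 with the non-neuronal marker level as a covariate, which was chosen after seeing the data. DESeq2 gave no adjusted p for 3960 of these 14587 genes. The genes nearest to the threshold included Tenm3, a synaptic adhesion molecule (ENSMUSG00000031561, chromosome 8, 48227682 to 48843951), at 438 ± 36.5 CPM in EE and 340 ± 31.2 in SH (log2 fold change 0.37 ± 0.06, adjusted p = 0.0753). Another was Abi3bp, a protein of the extracellular matrix (ENSMUSG00000035258, chromosome 16, 56477846 to 56690128), at 162 ± 30.9 and 76.6 ± 16.7 CPM (1.08 ± 0.17, adjusted p = 0.0976). Lrrc9 (0.64 ± 0.12), the transcription factor gene Tfap2d (0.89 ± 0.17) and the transporter gene Abca4 (0.48 ± 0.09) were the other leading genes above SH. Below SH lay the cell-surface proteoglycan gene Gpc6 (-0.33 ± 0.06), Iqgap2 (-0.39 ± 0.07), Grb14 (-0.32 ± 0.06), Stxbp6 (-0.32 ± 0.06) and Ccbe1 (-0.36 ± 0.07), each past the SH median in 6 of 6 EE libraries. The count of called genes rose to 85 without SH replicate 2, the library with the most glial RNA. It was 13 without EE replicate 1, 5 without SH replicate 1, 2 without SH replicate 6 and 1 without EE replicate 6.

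**Figure D2:**
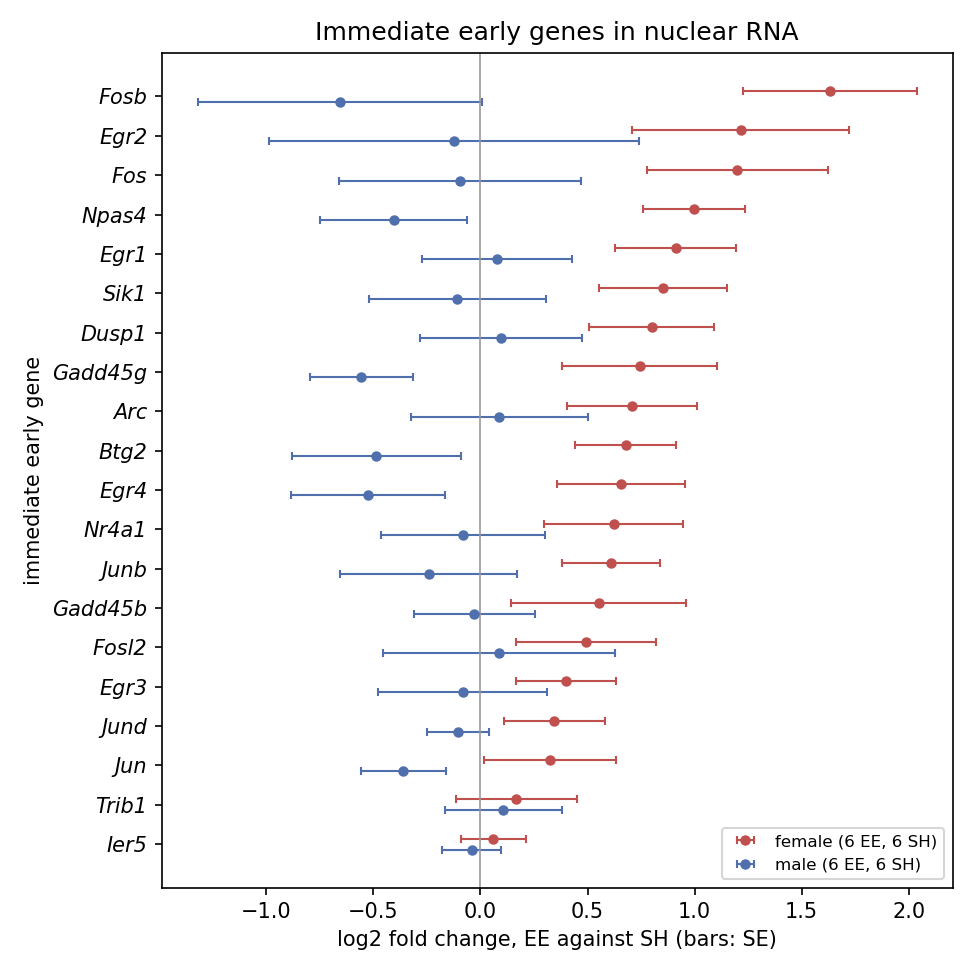
Log2 fold change (EE against SH) of each measured immediate early gene in female and male RNA, as points with SE, from 6 libraries per group. All 20 female values are above 0, and in males 15 of 20 are below 0.

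In males the same question gave 6 called genes, 5 that rose and 1 that fell with enrichment. Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126), which encodes the core clock transcription factor BMAL1, rose from 121 ± 5.38 CPM in SH to 141 ± 5.33 in EE (SD, n = 6 each; log2 fold change 0.22 ± 0.04, SE). Pcdh11x, an X-linked protocadherin (ENSMUSG00000034755, chromosome X, 120290259 to 120910619), rose from 127 ± 10.7 to 159 ± 10.2 CPM (0.33 ± 0.05). Robo3, an axon guidance receptor (ENSMUSG00000032128, chromosome 9, 37415669 to 37433246), rose from 37.8 ± 4.33 to 51.6 ± 5.05 CPM (0.45 ± 0.07). Trps1, a zinc finger transcription factor (ENSMUSG00000038679, chromosome 15, 50654752 to 50890463), rose by a log2 of 0.26 ± 0.04. Vmn2r85, a member of the vomeronasal receptor family that may share reads with its relatives (ENSMUSG00000092048, chromosome 10, 130417772 to 130429612), rose by 0.82 ± 0.14. Lypd1, which modulates nicotinic acetylcholine receptors (ENSMUSG00000026344, chromosome 1, 125867622 to 125913101), fell from 44.7 ± 2.60 to 36.7 ± 1.63 CPM (-0.28 ± 0.05).

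All 6 genes had an adjusted p of 0.0316 in edgeR (14597 tested, 1172 at an unadjusted p under 0.05), and each lay past the SH median in 6 of 6 EE libraries. DESeq2 called 61 genes, 5 of these 6 among them, and limma 0. DESeq2 gave no adjusted p for 11037 of the 14597 genes. No gene was called without EE replicate 3 or without SH replicate 1, 2, 3 or 4. The count was 2 without EE replicate 2, 11 without EE replicate 5, 1 with the striatal marker level as a covariate and 0 with 1 surrogate variable.

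**Figure D3:**
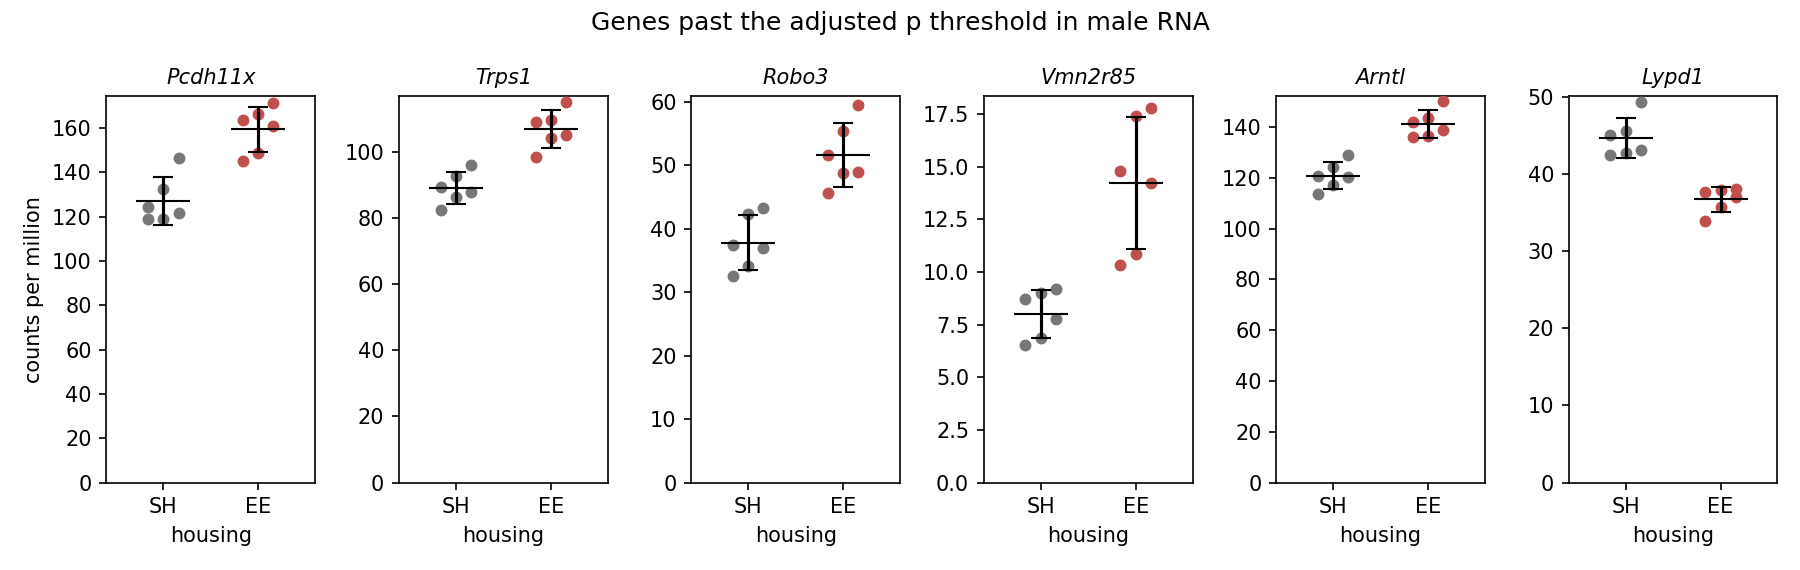
CPM of the 6 genes called in male RNA, each library as a point, with the mean and SD of the 6 EE and 6 SH libraries. Each EE point of Pcdh11x, Trps1, Robo3, Vmn2r85 and Arntl lies above the SH median of that gene, and each EE point of Lypd1 below it.

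Other male genes stood out within their list without passing over all genes. Of the clock list, 4 of 21 genes passed when adjusted over the list alone against 1 over all genes. Beside Arntl these were Clock, the partner of BMAL1 (log2 fold change 0.12 ± 0.04), and the clock output factors Dbp (12.8 ± 0.24 CPM in EE and 16.1 ± 1.56 in SH, -0.33 ± 0.07) and Tef (-0.15 ± 0.04). The list as a whole did not lean either way (13 of 21 higher, camera adjusted p = 0.959). In the mixed test of fry, where members may go either way, this list and the voltage-gated channels passed. Among voltage-gated channels the potassium channel gene Kcnc2 (0.21 ± 0.05), the sodium channel gene Scn1a (0.21 ± 0.05) and the T-type calcium channel gene Cacna1h (-0.22 ± 0.05) passed over the list alone and 0 over all genes (22 of 37 higher, adjusted p = 0.0718). So did the AMPA receptor gene Gria4 (0.21 ± 0.04; postsynaptic density, 23 of 40 higher, adjusted p = 0.125) and the glucocorticoid receptor gene Nr3c1 (0.17 ± 0.04; glucocorticoid-responsive genes, 11 of 14 higher, adjusted p = 0.188). These were 1 gene of each list. Striatal markers did not pass as a group (5 of 16 higher, adjusted p = 0.269).

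In male RNA 5 lists passed camera, all higher in EE, but each had adjusted p = 0.762 with an estimated correlation. These were astrocytes (20 of 24 genes, median 0.18, adjusted p = 0.00633), oligodendrocytes (18 of 21, 0.31, adjusted p = 0.0282) and upper-layer excitatory neurons (13 of 18, 0.09, adjusted p = 0.0282). The others were GABAergic interneurons (23 of 29, 0.09, adjusted p = 0.0319) and high-confidence autism genes (42 of 61, 0.02, adjusted p = 0.0319, with a median of -0.01 when scaled by total count alone). Each had 0 members past the threshold, over the list alone or over all genes. Examples are the astrocyte transporter genes Slc4a4 (0.14 ± 0.04) and Slc1a2 (0.13 ± 0.05), the myelin genes Mog (0.79 ± 0.30) and Ugt8a (0.38 ± 0.12), Epha3 (0.20 ± 0.06) and Adarb2 (0.12 ± 0.04). The level of the astrocyte list per library did not differ beyond its spread (0.06 ± 0.45 in EE and -0.06 ± 0.17 in SH, exact permutation p = 0.595). The number of lists past the test was 1 without EE replicate 3, 8 without EE replicate 4, 0 without EE replicate 6, 2 without SH replicate 2 and 3 without SH replicate 4.

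Immediate early genes did not pass in males (15 of 20 lower, median -0.10, camera adjusted p = 0.188; Btg2 -0.49 ± 0.39), nor did the remaining lists. Delayed activity-regulated genes were higher in 28 of 36 cases (adjusted p = 0.0507; Inhba 0.37 ± 0.12), neurotrophic genes in 18 of 28 (adjusted p = 0.125; Ntf3 -0.45 ± 0.16) and perineuronal net genes in 18 of 27 (adjusted p = 0.128). So were chromatin regulators in 48 of 80 (adjusted p = 0.128; Kdm7a 0.21 ± 0.06) and presynaptic genes in 20 of 39 (adjusted p = 0.556). Ribosomal protein genes (25 of 66 higher, adjusted p = 0.141), respiratory chain genes (29 of 72, adjusted p = 0.225), and deep-layer markers (10 of 27, adjusted p = 0.565; Crym -0.28 ± 0.10) had fewer genes higher than lower. Heat shock genes (12 of 27, adjusted p = 0.959), oligodendrocyte precursors (5 of 13, adjusted p = 0.656), microglia (8 of 16, adjusted p = 0.959) and vascular cells (5 of 13, adjusted p = 0.188) completed the set. Camera and the median differed in sign for the clock (median 0.01, mean -0.01) and heat shock genes (-0.00, mean -0.02), and the mean and the median for oligodendrocyte precursors (-0.04, mean 0.05).

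Whether enrichment acts differently in the 2 sexes was tested by the interaction of sex and housing across 15562 genes in both tables. Only 4921539H07Rik passed, with a log2 fold change of -0.58 in females and 0.08 in males (difference -0.66 ± 0.11, adjusted p = 0.0241). Next came Dnah11, an axonemal dynein gene, with 0.91 in females and -0.88 in males (adjusted p = 0.0504). The glucocorticoid receptor gene Nr3c1 had -0.19 and 0.17 (adjusted p = 0.0861). Neither passed, and both were chosen after their values were seen. For immediate early genes the median difference, female minus male, was 0.71 (camera adjusted p = 3.27e-07), but adjusted p = 0.473 with an estimated correlation and 0.352 by permuting housing within each sex. The interaction called 91 genes with DESeq2 and 39 without female SH replicate 2, the library with high glial markers. It called 10 without female EE replicate 1, 6 without female EE replicate 5, 7 without female SH replicate 6, 7 without male EE replicate 4 and 5 without male SH replicate 5. It called 2 without each of female EE replicate 4, female SH replicate 1, male EE replicates 2 and 5 and male SH replicates 1 and 4. It called 0 without each of female SH replicates 3, 4 and 5, male EE replicates 1 and 6 and male SH replicate 6.

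Across 14067 genes the log2 fold changes of females and males showed no correlation beyond that of relabelled housing (Pearson r = -0.0133, Spearman rho = -0.0353). The relabellings reached an r of 0.271 in size, so a modest shared change could be missed. Of 100 relabellings of housing, 91 gave an r as large and 62 a rho as large, and the adjusted p of r was 0.91 over 4 such relations. Genes are not independent replicates. A common effect of housing in 1 fit of both sexes, an analysis chosen after seeing the data, called Trps1 (0.25 ± 0.04, adjusted p = 0.00160) and Lmo7, a LIM and PDZ domain protein gene (0.24 ± 0.04, adjusted p = 0.0260). Trps1 was 0.24 in females and 0.26 in males, and Lmo7 0.33 and 0.15.

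In female chromatin, 57 regions were called more accessible and 21 less accessible in EE than in SH, and most of the strongest gains lay far from genes. Of the 10 splits of these libraries, 1 that mixed EE with SH called 111 regions, against 78 in the real split. The strongest gain, on chromosome 6 from 18628441 to 18629049 with Cttnbp2 as the nearest gene at 114 kb, averaged 8.68 ± 1.02 CPM in EE and 1.82 ± 0.25 in SH (SD, n = 3 each; log2 fold change 2.25 ± 0.21, adjusted p = 8.31e-12). A pair of regions on chromosome 3 near Sox2, a transcription factor of progenitors and glia, gained 1.83 ± 0.28 (34748191 to 34748721) and 1.96 ± 0.30 (34470670 to 34470948). Some of the losses lay inside genes. One was in Ntrk2, the receptor of BDNF (chromosome 13, 58924175 to 58925901, -0.90 ± 0.18). Others were in Rgs9, a regulator of G protein signalling that is abundant in striatum (chromosome 11, 109258305 to 109259613, -0.78 ± 0.14), Rap1gap (chromosome 4, 137691613 to 137692587, -0.76 ± 0.14) and Bhlhe40, a clock regulator (chromosome 6, 108666831 to 108669197, -0.64 ± 0.12).

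Further leading gains were on chromosome 16 from 71108578 (1.26 ± 0.18), chromosome 12 from 97917840 (0.89 ± 0.14), chromosome 6 from 23966507 (0.69 ± 0.11), chromosome 5 from 50204005 (0.70 ± 0.12) and inside Hecw2, a ubiquitin ligase gene, on chromosome 1 from 54106453 (0.92 ± 0.16). Further losses were inside Ranbp3l, an astrocyte marker, on chromosome 15 from 9015717 (-2.11 ± 0.27), inside the glycosyltransferase gene Galnt9 on chromosome 5 from 110594186 (-0.58 ± 0.11) and on chromosome 6 from 31104347 (-0.97 ± 0.17). The last lay within the span of Lncpint, which held 5 of the 21 losses. Another lay on chromosome Y from 90844298 (-1.81 ± 0.31), where the female table holds 53 regions with 24197 to 64901 counts per library. Male ATAC libraries hold 26994 to 64730 counts on Y, and the share on X was 1.89% to 2.05% in females and 1.72% to 2.02% in males, so these counts do not check the sex labels as the RNA does. Called regions near list genes also included the postsynaptic scaffold gene Homer1 (chromosome 13 from 93372855, -0.61 ± 0.13), Arc (chromosome 15 from 74675230, 2.66 kb from the start, -0.53 ± 0.11) and Btg2 (chromosome 1 from 134074171, 4.04 kb from the start, -0.99 ± 0.21).

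Of 164926 female regions tested with edgeR, 13204 had an unadjusted p under 0.05, DESeq2 called 122 and limma 54. DESeq2 gave no adjusted p for 95927 of the 164926 regions. None of the called regions lay within 1 kb of a protein-coding gene start, against 10.0% of all tested regions (Fisher's exact p = 0.00604 for gains and 0.261 for losses). Starts of other genes were not counted here. Inside protein-coding genes lay 11 gains and 10 losses. Every left-out library moved the count: to 166 without EE replicate 1, 26 without EE replicate 2, 24 without EE replicate 3, 333 without SH replicate 1, 22 without SH replicate 2 and 28 without SH replicate 3.

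As groups, regions near 8 lists were less accessible in female EE libraries, led by immediate early genes (274 of 369 regions lower, median -0.16, camera adjusted p = 2.26e-08) although the RNA of that list was higher. None of the 8 held with an estimated correlation: adjusted p = 0.301 for ribosomal proteins, 0.278 for delayed activity-regulated genes and 0.210 for each of the others. Heat shock genes followed (188 of 238, -0.13, adjusted p = 7.06e-06), then glucocorticoid-responsive genes (179 of 268, -0.12, adjusted p = 0.00120) and the clock (211 of 304, -0.11, adjusted p = 0.00120). Next were the postsynaptic density (584 of 880, -0.11, adjusted p = 0.00135) and oligodendrocytes (126 of 201, -0.11, adjusted p = 0.00252). The last were ribosomal proteins (301 of 457, -0.07, adjusted p = 0.0109) and delayed activity-regulated genes (425 of 699, -0.07, adjusted p = 0.0140). Sets of random genes with like numbers of regions were lower too, with medians of -0.03 to -0.06 for these 8 lists. In a test against them that was added after the data were seen, immediate early (1.15% of sets as far from the random median, adjusted over the lists) and heat shock genes (1.53%) stood apart. So did deep-layer markers in the higher direction (1.15%, median 0.0425 against -0.0446 for random sets), a list that did not pass camera. The postsynaptic density (5.51%), glucocorticoid-responsive genes, the clock, oligodendrocytes and ribosomal proteins (13% each) and delayed activity-regulated genes (77.6%) did not. Adjusted over the list alone, 7 regions of immediate early genes passed against 2 over all regions, 4 of delayed activity-regulated genes against 1, 3 of the postsynaptic density against 1, 2 of the clock against 1 and 1 of oligodendrocytes against 0.

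The other 15 lists did not pass in female ATAC. Lower in most regions were autism genes (711 of 1175, adjusted p = 0.0608), chromatin regulators (554 of 876, adjusted p = 0.0639), and channels (489 of 802, adjusted p = 0.0767). So were presynaptic genes (397 of 663, adjusted p = 0.0784), the respiratory chain (268 of 428, adjusted p = 0.0784), oligodendrocyte precursors (67 of 113, adjusted p = 0.172), neurotrophic genes (200 of 348, adjusted p = 0.185) and perineuronal nets (168 of 327, adjusted p = 0.935). Higher in most regions, or evenly divided, were microglia (83 of 121, adjusted p = 0.0636), deep-layer markers (193 of 341, adjusted p = 0.185), and upper-layer markers (177 of 316, adjusted p = 0.799). So were vascular cells (27 of 54, adjusted p = 0.935), GABAergic markers (157 of 300, adjusted p = 0.977), striatal markers (166 of 326, adjusted p = 0.977) and astrocytes (119 of 236, adjusted p = 0.995). Camera and the median differed in sign for GABAergic and striatal markers (medians 0.01). Adjusted over the list alone, 3 astrocyte regions against 1, 2 striatal regions against 1 and 2 neurotrophic regions against 0 passed.

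In male chromatin no region was called by edgeR (0 of 192834 tested with 6 EE and 7 SH libraries, 8746 at an unadjusted p under 0.05), and DESeq2 called 7 and limma 0. A fit with 1 surrogate variable called 21. Nearest to the threshold was another region inside Ntrk2, the BDNF receptor gene (chromosome 13, 58969843 to 58971287), at 1.45 ± 0.25 CPM in EE and 2.65 ± 0.50 in SH (log2 fold change -0.89 ± 0.15, adjusted p = 0.216, past the SH median in 6 of 6 EE libraries). A pair of regions near Parva, which links integrins to actin, were at -0.84 ± 0.15 and -0.61 ± 0.11 (chromosome 7, from 112355217 and from 112360504, adjusted p = 0.311). Above SH, regions on chromosome 16 from 93428642 (0.70 ± 0.13, adjusted p = 0.311), chromosome 7 from 145340931 (0.45 ± 0.09, adjusted p = 0.575) and chromosome 2 from 138140508 (0.60 ± 0.12, adjusted p = 0.698) led. Without SH replicate 6 the count was 3.

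No list passed in male ATAC. Lower in most regions were presynaptic genes (401 of 621, adjusted p = 0.0516), heat shock genes (100 of 160, adjusted p = 0.0983), autism genes (691 of 1133, adjusted p = 0.0983) and chromatin regulators (higher in 311 of 815, adjusted p = 0.0983). So were the postsynaptic density (477 of 767, adjusted p = 0.107), channels (489 of 826, adjusted p = 0.107), ribosomal proteins (246 of 397, adjusted p = 0.151), and immediate early genes (164 of 284, median -0.02, adjusted p = 0.331). The same held for the respiratory chain (205 of 370, adjusted p = 0.639), deep-layer markers (200 of 382, adjusted p = 0.676) and the clock (151 of 283, adjusted p = 0.742). It also held for glucocorticoid-responsive genes (128 of 242, adjusted p = 0.865), delayed activity-regulated genes (330 of 619, adjusted p = 0.927) and neurotrophic genes (233 of 435, adjusted p = 0.955). Higher in most regions were striatal markers (178 of 280, adjusted p = 0.0983), vascular cells (66 of 103, adjusted p = 0.151), astrocytes (126 of 221, adjusted p = 0.296) and oligodendrocyte precursors (82 of 139, adjusted p = 0.331). So were GABAergic markers (182 of 336, adjusted p = 0.408), perineuronal nets (216 of 389, adjusted p = 0.529), oligodendrocytes (98 of 186, adjusted p = 0.639), microglia (92 of 154, adjusted p = 0.639) and upper-layer markers (176 of 327, adjusted p = 0.676). With promoter regions alone, 4 lists passed, all lower, and 1 oligodendrocyte region passed when adjusted over the list alone against 0 over all regions.

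No common change was detected in the regions shared between the sexes, where relabellings of housing reached an r of 0.378 in size. Over 49875 regions that overlap by at least 50% of both, the log2 fold changes of females and males had a Pearson r of 0.0597 and a Spearman rho of 0.0641, which 60 and 64 of 100 relabellings of housing reached (adjusted p = 0.91 over the 4 relations). Of the 78 regions called in females, 36 had such a counterpart in males, and 20 of these had the same direction (binomial p = 0.618).

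Nor was a common change of RNA and promoter accessibility detected across genes. In females r was -0.0123 and rho -0.0384 over 10708 genes, reached by 70 and 43 of 100 relabellings. In males r was -0.0267 and rho 0.00197 over 10719 genes, reached by 55 and 96 (adjusted p = 0.91 for each r). RNA and ATAC come from different libraries, so no library can be compared with itself.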

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

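The tests with covariates, with libraries left out of the lists and with other splits of the libraries were chosen only after the results they concern were seen, while the tests of region sets were chosen before their outcome was known.

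Within groups of 4 to 10 libraries, the library at either end was compared with its neighbours for the leading genes, regions, lists and library measures, in 158 comparisons, and 13 values stood apart, where chance gives about 1 in 20. Female SH replicate 2 held 8 of them: the levels of astrocytes (1.22), oligodendrocytes (1.41), oligodendrocyte precursors (0.97), microglia (1.3), vascular cells (1.46) and these lists together (1.29) were above the other 5 SH libraries, and Gpc6 (752 CPM) and Iqgap2 (105 CPM) were below them. Male EE replicate 1 was low for microglia (-0.67) and for GABAergic interneurons (-0.31). The others were the neurotrophic list in male SH replicate 4 (0.0530), the region on chromosome 16 from 93428642 in male ATAC SH replicate 6 (1.1615 CPM), and the total count of female RNA SH replicate 3 (10.6 M).

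The test of a different effect of housing in the sexes called 1 gene and 7 lists, but with an estimated correlation none of the 7 passed (the smallest adjusted p was 0.473). For 4921539H07Rik the difference of log2 fold changes, female minus male, was -0.66, and 6 of 100 splits of the same libraries gave as many called genes (1 in the real split, 12 in the highest other), so chance cannot be excluded for this count. For the lists the median differences were 0.71 (immediate early genes), 0.49 (striatal projection neurons), 0.18 (cytosolic ribosomal proteins), -0.16 (upper-layer excitatory neurons), -0.0627 (excitatory postsynaptic density), -0.0639 (high-confidence autism genes) and -0.0482 (voltage-gated channels). None passed by permuting housing within each sex (the smallest adjusted p was 0.101). As many lists were past the test in 44 of 100 splits (7 in the real split, 17 in the highest other), so chance cannot be excluded here either.

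Higher RNA of immediate early genes in female EE libraries may follow from neuronal activity before the tissue was taken, a biological explanation that no measurement here tests, since wheel running and the hour of collection are not recorded per library. Striatal nuclei as the whole source are argued against, because the median log2 fold change was 0.69 with the striatal marker level as a covariate against 0.67 without it. A share of non-neuronal nuclei is argued against in the same way (0.67 with that covariate). What SH replicates 1 and 4 contribute stays open, since their levels were the lowest (-0.90 and -0.89) and the median was 0.54 without SH replicate 4, the lowest with 1 library left out, and 0.43 without both, with an exact permutation p of 0.0524 for the level per library. In 1 of 100 splits, the real one, the camera p of this list was as small, but another split came close (1.66e-15 and 5.63e-15). Over the lists the adjusted p was 0.156 for the level per library, 0.154 with fry and 0.255 with an estimated correlation. Chance cannot be excluded by these tests, which do not pair libraries by number, and differences in handling between the 2 kinds of cage stay open.

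Regions of immediate early genes were less accessible in female EE libraries, opposite in sign to the RNA, but with an estimated correlation the adjusted p was 0.210. Their promoter share and abundance do not account for it, because the median log2 fold change was -0.15 after subtracting the median of regions of like promoter status and abundance. Random sets of genes with like numbers of regions were lower too (median -0.0464), but 0.0999% of 1000 sets, the smallest share these draws can give, had a median as far from 0, and the share adjusted over the lists was 1.15% when measured from the median of the random sets. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and the real split gave the smallest camera p (9.85e-10, the next 4.26e-08), in 1 of 10. No biological explanation was tested, and accessibility and RNA were measured in different libraries.

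In male RNA 1 of 100 splits, the real one, called as many genes (6, against 4 in the highest other). That share argues against chance, but it is not corrected over the other counts compared this way, so chance is not excluded. Limma and the fit with 1 surrogate variable called 0 genes. In female RNA the real split called 0 genes, which each of the 100 splits reaches by construction, so that share tests nothing. The highest other split called 71, which by itself points to differences between these libraries other than housing. Lists past camera reached the real number in 76 of 100 splits of female RNA (4 and 18) and 77 of 100 of male RNA (5 and 18), so chance cannot be excluded for the number of lists. In female ATAC the 10 splits are too few for a share under 0.05: 2 gave as many regions (78 real, 111 highest other) and 2 as many lists (8 and 8). In male ATAC the real split gave 0 regions and 0 lists, which each of the 24 splits reaches by construction, so those shares test nothing either (the highest others were 5 and 12). The common effect of housing on RNA called 2 genes in the real split and at most 1 in the others, so 1 of 100 splits reached it. This fit was chosen after seeing the data and the share is not corrected over the other counts, so chance is not excluded.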

How the results depend on the processing

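The tests with covariates, the joint fit, male ATAC without SH libraries 5 and 6, female RNA without SH libraries 1 and 4, the nearest gene of any class, and the left-out libraries for lists and for the interaction were chosen only after the results were seen.

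The number of called genes in female RNA was 0 with DESeq2 size factors and with a stricter filter, but 1 when scaled by total count alone, 168 with no count filter, 117 with DESeq2, 19 with limma, 42 with 1 surrogate variable, 17 at a threshold of 0.1, 1 with the striatal and 36 with the non-neuronal marker level as a covariate, 49 in the joint fit, and 0 to 85 with each library left out (85 without SH replicate 2), and 1 without SH libraries 1 and 4. In male RNA, where 6 genes were called, it was 136 with no count filter, 61 with DESeq2, 0 with limma, 0 with 1 surrogate variable, 11 at 0.1, 1 with the striatal covariate, 1 in the joint fit, and 0 to 11 with each library left out (0 without EE replicate 3, 11 without EE replicate 5), and within 1.5 times of 6 in the other settings except the replicate block. The cause was not tested.

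For the 78 regions of female ATAC the count was 120 with a stricter filter, 122 with DESeq2, 44 with 1 surrogate variable, 254 at a threshold of 0.1, and 22 to 333 with each library left out (22 without SH replicate 2, 333 without SH replicate 1), and 54 to 101 with limma, other scalings, loess offsets, no filter and autosomes only. For male ATAC, with 0 regions called by edgeR (8746 at an unadjusted p under 0.05), it was 7 with DESeq2, 21 with 1 surrogate variable, 2 without SH libraries 5 and 6, 0 to 3 with each library left out (3 without SH replicate 6), and 0 in the other settings except the replicate block. The cause was not tested.

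The labels do not say that libraries of the same replicate number share an animal, litter or day, and not every such pair varied together. The columns of the female RNA table do carry matching numbers in both groups. Those of the male RNA table mostly carry different numbers for the same replicate number. The replicate number was used here, so pairs by column number were mostly not tested in that table. After the mean of each group was removed, libraries of the same replicate number correlated above 0.1 in 5 of 6 pairs of female RNA (0.0265 to 0.36), 0 of 3 of female ATAC, 2 of 6 of male RNA and 3 of 6 of male ATAC. In female RNA 6 of 12 libraries correlated best with their own number, where each had 6 libraries of the other group to choose from. This is a hint from the data that leaves a shared factor open there. With the replicate block the counts were 95 for female RNA, 3 for male RNA, 34 for female ATAC and 1 for male ATAC.

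Lists past the test numbered 0 with an estimated correlation and 0 with fry (directional) in both RNA tables, and 0 with an estimated correlation in female ATAC. In female RNA, with 4 lists, 2 passed when scaled by total count alone and 2 to 13 with each library left out (2 without EE replicate 6, 13 without SH replicate 2), and 6 without SH libraries 1 and 4. In male RNA, with 5, 0 to 8 did (0 without EE replicate 6, 8 without EE replicate 4). In the mixed test of fry, where members may go either way, 4 lists passed in female RNA (immediate early genes, adjusted p = 0.0282, upper-layer neurons, 0.00317, chromatin regulators, 0.00140, and autism genes, 0.0425) and 2 in male RNA (channels and the clock, 0.00356 each). With promoter regions only 12 lists passed in female ATAC, against 8, and 4 in male ATAC, against 0, and with the nearest gene of any class 10 and 0 did. The interaction called 91 genes with DESeq2 and 0 to 39 with each library left out (0 without female SH replicate 3, 39 without female SH replicate 2). The Pearson r of the 4 correlations kept its sign and, where housing was relabelled, stayed within the range of the relabellings. The Spearman rho of male RNA and promoters changed from 0.00197 to -0.00264 with the nearest start within 10 kb.

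Of 5014 values of the 223 named genes and regions under alternatives, 4720 kept direction and side of the threshold, 114 kept direction and no longer passed, 159 kept direction and passed, and 21 reversed. None of the reversed genes was called. With limma, female RNA Mecom (0.0683), female RNA Abcb1a (0.198) and female RNA Pdgfrb (0.187) reversed, and Pdgfrb was 0.00416 with the replicate block and 0.000364 with the non-neuronal covariate. With each library left out, Mecom ran from -0.47 to 0.29, Abcb1a from -0.32 to 0.30, female RNA Gjc3 from -0.66 to 0.0246, female RNA Pecam1 from -0.23 to 0.0423, Pdgfrb from -0.21 to 0.31 and female RNA Xist from -0.0931 to 0.0279, each highest without SH replicate 2. Abcb1a (0.0675) and Xist (0.00949) also reversed without EE replicate 6. In males, male RNA Rgs9 was -0.000213 with 1 surrogate variable, male RNA Eif2s3y 0.00344 with no count filter and -0.0283 to 0.0225 with libraries left out, and male RNA Uty -0.000369 when scaled by total count alone and -0.000324 to 0.0646 with libraries left out.

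Small changes in ATAC were mostly missed in data simulated at the depth, spread and number of libraries of these tables, which the simulation does not separate. A log2 change of 0.5 was called in 6% of changed regions in females and 26% in males. These shares hold for 200 changed regions drawn independently, and other numbers of changed regions were not simulated. Offsets for GC content and the motif content of regions were not run.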

Other observations

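The sterol list, its test in females, the tests of Ntrk2 regions and astrocyte regions in females, the sums over gene bodies and the other loci were chosen only after related results were seen.

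Genes of sterol synthesis may be higher in EE in males, a pattern noticed from single genes (among them Srebf2 0.17 ± 0.04, Msmo1 0.36 ± 0.09 and Hmgcs1 0.35 ± 0.13, log2 fold change with SE), none of which passed over all genes. Without the genes first noticed, 18 of 19 genes of the list were higher in male EE libraries (median 0.19; Idi1 0.54 ± 0.21, Sqle 0.28 ± 0.10), with an exact permutation p of 0.0130 for the level per library. Non-neuronal nuclei as the whole source are argued against by a median of 0.20 with the non-neuronal marker level as a covariate. In females, which played no part in choosing the list, 23 of 24 genes were higher (median 0.17, exact permutation p = 0.0216), which argues against a difference found in males alone by looking at many genes. These p values are not corrected for the other lists that could have been written, so this stays a hypothesis.

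Counts summed over the regions inside each gene body, away from starts, called 24 of 6451 genes in females and 0 of 6823 in males with edgeR (140 at an unadjusted p under 0.05). Of the female genes 16 were higher in EE, among them Slc25a21 (0.59 ± 0.11) and Gulp1 (0.75 ± 0.16), and 8 lower, among them Cmip (-0.33 ± 0.06), Bhlhe40 (-0.50 ± 0.09) and Ntrk2 (-0.29 ± 0.06). Of 23 that could be tested in males, 14 had the same direction (binomial p = 0.405). The 10 splits of the female libraries are too few for a share under 0.05: 1 of them, the real one, reached 24, and the highest other called 2. In males the real split called 0, which each of the 24 splits reaches by construction, so the share tests nothing. The highest other split called 682, which by itself points to differences between these libraries other than housing.

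Across the Ntrk2 gene 104 of 118 regions were lower in EE in females (88.1%, exact permutation p = 0.1 for the summed counts, the smallest possible) and 95 of 127 in males (exact permutation p = 0.234). The median log2 fold change of astrocyte regions in females was 0.00366. From Mir29a to Lncpint 92 of 93 regions were lower in females and 10 of 15 in males (exact permutation p = 0.683). At Homer1 69 of 76 were lower in females and 11 of 30 in males.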
